A study of Zea mays with 12 samples.

How the data were processed

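RNA of maize (Zea mays) whole plants was measured in 12 libraries, 3 in each of 4 groups. The labels give each library a treatment, CK or BV-3, where BV-3 is a Bacillus strain and CK is the untreated control, and a disease class, susceptible or resistant. The labels call the 3 libraries of a group separate biological samples. Per the labels' protocols, messenger RNA was selected by its poly(A) tail and sequenced from strand-specific libraries as paired reads. The times of harvest and the age of the plants are not given in the sources used here.

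The authors deposited 1 table for the whole series with, per gene and library, a raw count and an FPKM value (fragments per kilobase of gene model and per M mapped fragments), per the file headers. The deposited counts were whole numbers whose totals ranged from 27 to 37.8 M (mega) per library. The FPKM values were normalised by the authors and summed to between 523796 and 570604 per library. The aligner, the counter and whether counting used strand are not given in the sources used here, so reads shared between near-identical genes, overlapping genes or antisense partners could have been split or assigned to either gene. The submitters' processing notes name the genome build B73 RefGen, version 4, while the identifiers in the table are of the form used for a later annotation of the same line. No coordinates are given for that reason.

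The table held 52934 lines, of which 2 were stray lines that named no gene and were dropped. The remaining 52932 genes comprised 39756 annotated identifiers and 13176 models beyond the annotation, whose names begin with NewGene and which took 2.43 to 4.25% of the counts of a library. Gene names were taken from the descriptions in the table, and 30608 genes had an informative one. None of the identifiers matched the reference gene table of the assembly Zm-B73-REFERENCE-NAM-5.0 (0 matched), whereas 32306 genes had a symbol in the deposited table that this reference also lists.

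Raw counts were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) after trimmed-mean (TMM) scaling and edgeR's own filter on low counts, which kept 34291 genes. All 12 libraries entered 1 fit of 4 group means with no replicate block, because 3 libraries per group leave few degrees of freedom for the spread. The common biological coefficient of variation was 0.682. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The 5 comparisons were BV-3 against CK within each disease class, the difference of these effects, and resistant against susceptible under CK and under BV-3. Standard errors of log2 fold changes were derived from the test's F value. The design fixed before the data were examined foresaw limma on log2(FPKM + 1), and edgeR if the table also held raw counts, as it did.

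Gene lists, 35 in all, were fixed before the data were examined as search patterns over gene descriptions. They covered defence, hormones, secondary metabolism, nutrition, growth and markers of tissues and of the circadian clock. Some patterns caught members outside the theme, and the clock list held 2 genes that matched only by letters inside a longer word. Lists with at least 5 tested genes were tested with camera (limma 3.58.1) on log2(FPKM + 1) with a preset inter-gene correlation of 0.01 and, beside it, with an estimated correlation. Values adjusted over the lists are given. The fry test of limma was also planned and run for the lists, and its values are not given here. KEGG pathways with at least 15 tested genes, 124 in all, were taken from the annotation in the table and tested alike.

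The genes named in the text follow a rule fixed before the data were examined. For BV-3 against CK it takes the 10 largest rises and the 10 largest falls among called genes whose groups of 3 do not overlap, with a mean of at least 5 FPKM in the higher group and an informative name. For the other comparisons it takes 5 and 5. For each list it takes up to 4 members with the smallest p and a mean of at least 1 FPKM, and examples were drawn from these. Where a comparison called no gene, only the list members were named. The genes that single out libraries or the clock, and those taken from the fit of the 6 BV-3 libraries alone, were chosen after their values were seen.

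Where all libraries of a group had 0 counts, the fold is a lower bound against a floor of 3 counts per library, which covers counting error only. Replicate libraries were compared to look for a library deposited more than once. The mean chi-square per gene between replicates ranged from 72.3 to 495, far above sampling noise, and all libraries were kept as separate samples.

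The gene test was tried on counts simulated from the mean level of each of the 34291 genes, their fitted dispersions and the library sizes, with 200 abundant genes changed per comparison. In BV-3 against CK among susceptible libraries it recovered 0 of 67 genes changed 2-fold, 10.4% of 67 changed 4-fold and 66.7% of 66 changed 16-fold, with 0 false calls. In the resistant libraries 60.6% of 66 genes changed 16-fold were recovered, with 1 false call. Between the lines it recovered 57.6% of 66 such genes under CK, with 1 false call, and 65.2% under BV-3, with 0. A fit of the 2 compared groups alone recovered 25 to 29 of the 66 genes changed 16-fold and at most 1 of the 67 changed 4-fold. Apart from the changed genes, all simulated libraries shared the same mean level per gene. They held no line difference and no library against its label, so the false calls do not cover calls that arise from these. A simulated 2-fold rise of the 128 WRKY genes gave an adjusted p of 2.13e-18 with the preset correlation and 0.00012 with the estimated one, and 0 of the 34 other lists were called. This list trial used the log2 of counts per M plus 1 in place of log2(FPKM + 1). Genes were simulated independently of each other, so it cannot tell how often the preset correlation calls lists falsely among correlated genes.

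The alternatives tried were DESeq2 1.42.0, limma on FPKM or TPM under other pseudocounts, filters, scalings and library weights, other size factors, no filter on low counts, the 2 compared groups alone, a replicate block, stricter thresholds and leaving out each library. Other splits of the libraries were also tested. Data were read with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.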

Results

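The series measured gene expression in whole maize plants with and without inoculation with the Bacillus strain BV-3, in a susceptible and a resistant disease class. The 4 groups, CK susceptible, BV-3 susceptible, CK resistant and BV-3 resistant, had 3 libraries each. Total counts were 34.6, 30.4 and 36.0 M in the libraries labelled CK susceptible, 37.8, 36.5 and 32.3 M in BV-3 susceptible, 27, 30.2 and 29.7 M in CK resistant and 36.8, 37.4 and 35.1 M in BV-3 resistant, and between 33605 and 37691 genes had a count. Values are given as mean FPKM ± SD over the 3 libraries of a group, and log2 fold changes with their standard error from edgeR's quasi-likelihood test.

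The disease classes differed in genes that had counts in one and almost none in the other. Both classes were counted on 1 set of gene models. Here and below, a gene without counts was therefore not told apart from a gene whose reads failed to map. Among the BV-3 libraries, 246 genes were present above 2 CPM in each susceptible library with at most 2 counts in any resistant one, and 339 genes showed the opposite. The first library labelled CK susceptible had 98% of the susceptible markers above 1 CPM and 0.6% of the resistant ones. The second library labelled CK susceptible had 0.8% of the susceptible markers and 94.4% of the resistant ones, and the third had 1.6% and 95%. The libraries labelled CK resistant had 93.8 to 97.6% of the resistant markers and at most 1.2% of the susceptible ones. The second and the third library labelled CK susceptible thus went against their label, and groups are named below by their labels. The second library labelled CK resistant also stood apart. Its photosynthesis genes had a median centred log2(FPKM + 1) of -3.13 against -0.72 to 1.29 in the 11 other libraries, and its cytosolic ribosomal protein genes reached 2.23 against at most 0.4.

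**Figure D1:**
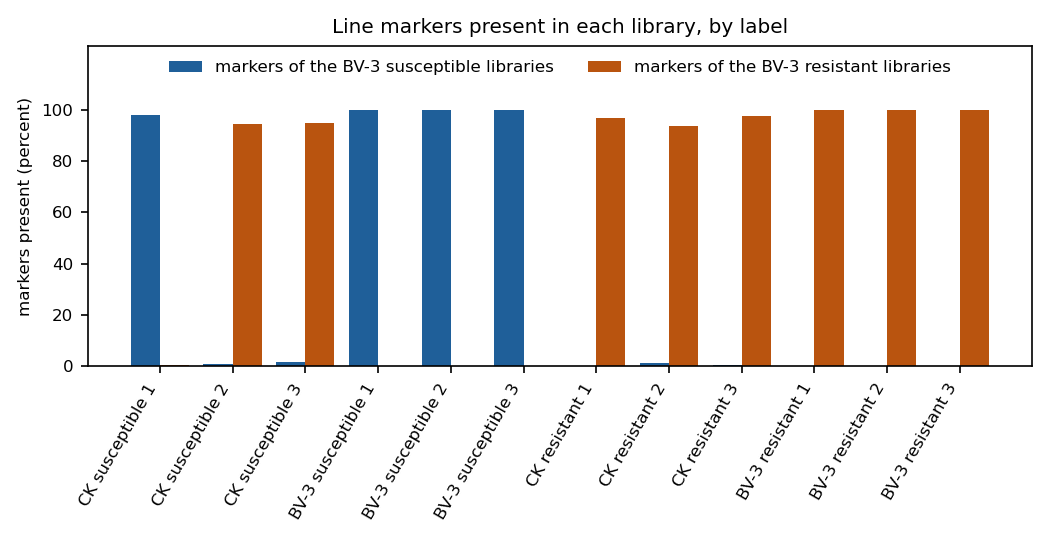
Percent of the 246 markers of the BV-3 susceptible libraries and of the 339 markers of the BV-3 resistant libraries present above 1 CPM in each of the 12 libraries, named by label and replicate. The second and the third library labelled CK susceptible show 94.4 and 95% of the resistant markers, and the BV-3 libraries stand at 0 or 100% because the markers were defined in them.

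The response of susceptible maize to BV-3 was addressed by comparing the libraries labelled BV-3 susceptible and CK susceptible. Clock genes differed between BV-3 and CK libraries, as given below, so a different time of harvest was not separated from BV-3. Genes of jasmonate, ethylene and WRKY signalling were higher as lists with camera's preset correlation (adjusted p = 5.83e-09, 3.93e-07 and 5.83e-09), and were not called with an estimated one (adjusted p = 0.695 with an estimated correlation for each). Allene-oxide cyclase2 (Zm00001eb393530), an enzyme of jasmonate synthesis, rose from 8.51 ± 6.95 to 88.6 ± 21.7 FPKM (log2 fold change 3.33 ± 0.65, adjusted p = 0.0398). Protein TIFY 11e (Zm00001eb048770), of the family of jasmonate signalling repressors, rose from 12.6 ± 14.2 to 217 ± 56.3 FPKM. Ethylene-responsive transcription factor 4 (Zm00001eb150840) rose from 44.0 ± 11.9 to 215 ± 51.1 FPKM, and putative WRKY transcription factor 46 (Zm00001eb395130) from 0.614 ± 0.227 to 11.3 ± 3.9 FPKM. In the first library labelled CK susceptible, whose line markers matched its label, these 4 genes stood at 16.4, 29.0, 48.5 and 0.408 FPKM.

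Among the largest rises, putative transcription factor bHLH041 (Zm00001eb284130) went from 0.0172 ± 0.0299 to 7.54 ± 4.45 FPKM (log2 fold change 8.46 ± 1.75, adjusted p = 0.0398). A jasmonate O-methyltransferase (Zm00001eb199360), which makes the volatile methyl ester of jasmonate, rose from 0.27 ± 0.434 to 35.0 ± 12.3 FPKM. Alternative oxidase AOX3 (Zm00001eb071870) rose by 6.35 ± 1.1 on the log2 scale, ABC transporter G family member 36 (Zm00001eb357950) by 6.11 ± 1.44 and WRKY transcription factor 1 (Zm00001eb052670) by 6.04 ± 1.19. Protein DMP3 (Zm00001eb371930), m15 protein (Zm00001eb214750), pyruvate decarboxylase 1 (Zm00001eb351810), the amino acid transporter LHT1 (Zm00001eb261480) and tyrosine N-monooxygenase (Zm00001eb385020) rose by 7.77, 6.01, 5.99, 5.56 and 5.26. Tyrosine N-monooxygenase reached 33.0 ± 7.89 FPKM from 0.816 ± 0.972. Some rises were uneven over the BV-3 susceptible libraries. AOX3, WRKY transcription factor 1 and LHT1 were highest in the third, at 103, 43.3 and 181 FPKM, with 10.7, 6.81 and 21.6 in the first. Pyruvate decarboxylase 1 and m15 protein were highest in the second, at 66 and 13.8 FPKM, with 12.2 and 0.694 in the third. The first library labelled CK susceptible was the highest of its group for all 10 genes, so the rises were smaller against it. It had 0.0517 FPKM of bHLH041, 0.102 of DMP3, 0.77 of the jasmonate O-methyltransferase, 0.969 of AOX3, 0.213 of the ABC transporter, 0.537 of WRKY transcription factor 1, 0.181 of m15 protein, 1.21 of pyruvate decarboxylase 1, 3.75 of LHT1 and 1.91 of tyrosine N-monooxygenase.

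The largest falls were of a different kind. A zinc finger gene of the RICESLEEPER type (NewGene_17548) had 37.1 ± 37.9 FPKM under CK and 0 counts in each BV-3 susceptible library, at least 1090-fold lower, but only 0.081 FPKM in the first library labelled CK susceptible. Cyclin-A3-2 (NewGene_24712) was at least 214-fold lower and vacuolar protein sorting-associated protein 9A (Zm00001eb015830) at least 146-fold lower, with 0.162 and 0.0243 FPKM in that first library. DEAD-box ATP-dependent RNA helicase 7 (Zm00001eb391860), probable methyltransferase PMT15 (Zm00001eb022840) and protein RADIALIS-like 3 (NewGene_9202) fell by 9.95, 7.4 and 7.87 on the log2 scale and were at 0.0851, 0.0805 and 0.873 FPKM there. By contrast, arginine decarboxylase 2 (Zm00001eb185400), an enzyme of polyamine synthesis, fell from 54.1 ± 5.48 to 0.0326 ± 0.0177 FPKM, with 57.6 FPKM in the first library labelled CK susceptible. Glutaredoxin-C1 (Zm00001eb131840) was at least 109-fold lower, with 14.3 FPKM there. Amino acid transporter AVT1C (Zm00001eb278120) and LOB domain-containing protein 37 (Zm00001eb051620) fell by 8.69 and 8.54, with 4.07 and 6.56 FPKM there.

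**Figure D2:**
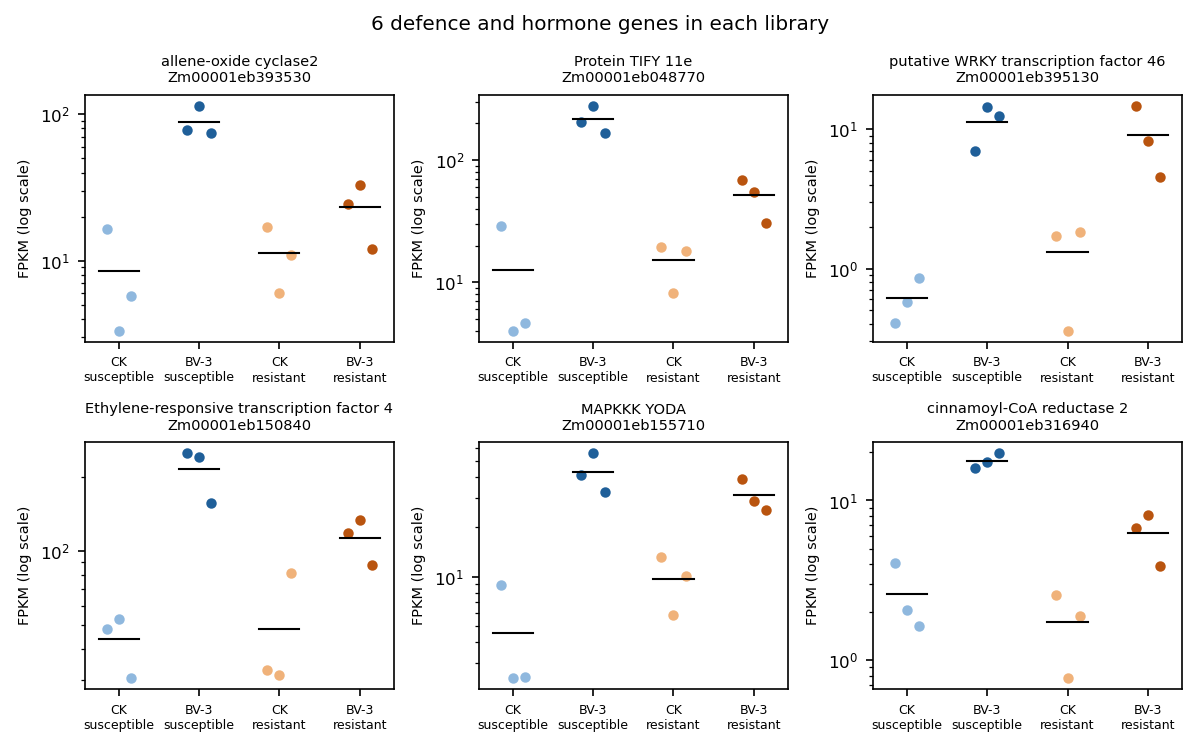
FPKM on a log scale of 6 genes of the jasmonate, WRKY, ethylene, MAP kinase and phenylpropanoid lists in each library, with a line at the group mean of 3 libraries. Allene-oxide cyclase2 has a mean of 88.6 FPKM under BV-3 and 8.51 under CK in the libraries labelled susceptible.

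By list, the jasmonate genes had a median log2 fold change of 1.56, with 9 of 76 risen and 1 fallen, and 24 risen and 4 fallen when adjusted over the list alone. Their median centred log2(FPKM + 1) was 0.08 in the first library labelled CK susceptible, against -0.98 and -0.89 in the 2 whose markers went against their label and 0.47 to 1.06 under BV-3, so the shift was smaller against the library that matched its label. Without those 2 libraries the list had an adjusted p of 6.38e-05. Of 128 WRKY genes 13 rose and 1 fell (34 and 5 adjusted over the list alone, median 1.41, or 1.39 with genes absent from a group at their bound), including probable WRKY transcription factor 4 (Zm00001eb149550) at 3.13 ± 0.51. Of 175 ethylene genes 15 rose and 1 fell (24 and 2 adjusted over the list alone, median 1.28, or 1.2 at the bound), with ethylene-responsive transcription factor ERF109 (Zm00001eb100800) at 2.3 ± 0.42. The MAP kinase cascade had 10 rises and 2 falls among 77 genes (19 and 6 adjusted over the list alone), among them the YODA kinase (Zm00001eb155710) at 3.2 ± 0.58 and salt-induced MAP kinase 1 (Zm00001eb393610) at 1.34 ± 0.28. Phenylpropanoid and monolignol synthesis, the route to lignin, had 8 rises and 2 falls among 98 genes (21 and 3 adjusted over the list alone), with cinnamoyl-CoA reductase 2 (Zm00001eb316940) at 2.74 ± 0.51, caffeoyl-CoA O-methyltransferase 1 (Zm00001eb271480) at 1.96 ± 0.39 and a related methyltransferase (NewGene_26074) at 3.77 ± 0.71. Flavonoid synthesis had 5 rises and 1 fall among 81 genes (7 and 1 adjusted over the list alone), with flavanone 3-dioxygenase 2 (NewGene_9844) at 3.56 ± 0.67 and a gene described as helminthosporium carbonum susceptibility 1 (Zm00001eb038160) at 2.51 ± 0.5. All 6 lists were called with the preset correlation and none with an estimated one (adjusted p = 0.695 to 0.698 with an estimated correlation).

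Pattern-triggered immunity genes had 5 rises and no fall among 111 (9 and 2 adjusted over the list alone), including calmodulin-like protein 1 (Zm00001eb141130) at 2.07 ± 0.44 and somatic embryogenesis receptor-like kinase 2 (Zm00001eb244860) at 1.92 ± 0.37. In the gibberellin and brassinosteroid list 4 of 70 rose (0 adjusted over the list alone), among them gibberellin 2-beta-dioxygenase 7 (Zm00001eb077080), which inactivates gibberellin, at 3.65 ± 0.81 and the receptor GID1 (Zm00001eb287800) at 2.55 ± 0.64. In the abscisic acid list 4 of 82 rose (1 adjusted over the list alone, median 0.74, or 0.66 at the bound), with dehydrin COR410 (Zm00001eb250120) at 3.15 ± 0.82 and Lea14-A (Zm00001eb344820) at 1.83 ± 0.37. Cell wall expansion genes had a median of 0.84 with 1 rise and 2 falls among 98 (0 adjusted over the list alone), where beta-expansin 1a (Zm00001eb391450) and xyloglucan endotransglycosylase homolog 1 (Zm00001eb226470) fell by 2.84 and 3.53. None of 38 terpenoid genes passed (0 adjusted over the list alone, median 1.17, or 1.05 at the bound), with ent-kaurene synthase B (Zm00001eb071080) at 3.07 ± 0.86 and an adjusted p of 0.0563. Photosynthesis genes had a median of -1.20 with 3 falls among 88 (0 adjusted over the list alone), including a PSB27-H2 protein (Zm00001eb214960) at -2.63 ± 0.66 and OHP1 (Zm00001eb168820), which was at least 128-fold lower but had 0 FPKM in the first library labelled CK susceptible. Cytosolic ribosomal proteins had 1 rise and 25 falls among 357 (1 and 27 adjusted over the list alone, median -0.47), with L23 (Zm00001eb197600) at -3.28 ± 0.65 and S4-3 (Zm00001eb321280) at -6.33 ± 1.28, which stood at 2.94 and 0.136 FPKM in that first library against 1.55 and 0.153 under BV-3. These 7 lists and the 6 before them were the 13 called, 11 higher and 2 lower under BV-3, with adjusted p from 5.83e-09 to 0.0456. None was called by camera with an estimated correlation (adjusted p = 0.695 to 0.712).

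In all, 2125 of 34291 genes were called with edgeR, 789 higher and 1336 lower under BV-3, and 9154 had an unadjusted p under 0.05. Of the calls 37.1% were higher, whereas limma on FPKM under other scalings, filters and pseudocounts gave 57.7 to 75.6% higher. The groups did not overlap in 1575 of the calls, and in 32.7% of all genes against 10% by chance. Of the calls 1171 (55.1%) were also called between the lines in a fit of the 6 BV-3 libraries, where 16.8% of 31752 genes were called, but both comparisons share the BV-3 susceptible libraries, which by itself raises the overlap. Line markers made up 304 of the calls. In the resistant libraries 81.9% of the calls had the same direction, and 608 also had no overlap between BV-3 and CK there. These shares were not taken over all genes, so they are no test of a shared response. Over all 34291 genes the BV-3 effects in the classes had a Pearson correlation of 0.245. A group was at 0 in every library for 523 calls, 504 of them the BV-3 group. Without the 2 libraries whose line markers went against their label edgeR called 0 genes, with 2330 at an unadjusted p under 0.05, and 1 gene without these and the second library labelled CK resistant. These smaller sets left 1 CK susceptible library, assumed to vary like the other groups, and called 12 lists each. The cell wall expansion (adjusted p = 0.765 and 0.931) and terpenoid lists (0.334 and 0.478) were lost in both, and the abscisic acid list in the smaller (0.0445 and 0.0632). The count rose to 7139 without the first library labelled CK susceptible. That run kept only the 2 CK susceptible libraries that carried resistant markers, so line and BV-3 could not be told apart in it. Line markers made up 569 of its calls. The count rose to 5493 without the second library labelled CK resistant. It fell to 109 without the third BV-3 resistant library, 53 without the first CK resistant, 4 without the second BV-3 resistant, 1 without the second CK susceptible and 0 without any one of the 6 others, which were the third CK susceptible, the third CK resistant, all 3 BV-3 susceptible and the first BV-3 resistant libraries.

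The response of resistant maize was addressed by comparing the libraries labelled BV-3 resistant and CK resistant, where time of harvest was likewise not separated from BV-3. WRKY, jasmonate, phenylpropanoid, flavonoid and aquaporin genes were higher as lists under BV-3 with camera's preset correlation (adjusted p = 2.2e-10 to 1.15e-07), although edgeR called no single gene over all genes tested. None of these lists was called with an estimated correlation (adjusted p = 0.223 to 0.398 with an estimated correlation). The second library labelled CK resistant was the lowest of its group for WRKY (-0.69 against -0.26 and 0.05 as median centred log2(FPKM + 1)), jasmonate (-1.2 against 0.01 and -0.45), phenylpropanoid (-0.67 against -0.21 and -0.02) and flavonoid genes (-0.77 against -0.22 and 0.05), but not for aquaporins. Without it and the 2 libraries whose markers went against their label, the lists had an adjusted p of 0.000682 for WRKY, 0.000365 for jasmonate, 0.000152 for phenylpropanoid, 0.000937 for flavonoid and 6.13e-07 for aquaporin genes. A pair of WRKY24 genes (Zm00001eb441670 and Zm00001eb149300) stood at 57.9 ± 28.2 and 53.5 ± 27.2 FPKM under BV-3 against 7.17 ± 3.44 and 6.89 ± 3.8 under CK (log2 fold change 3.08 ± 0.56 and 3.02 ± 0.59, adjusted p = 0.254 for both). Adjusted over the list alone, both passed among 128 WRKY genes (median 0.64). Among 76 jasmonate genes 4 passed adjusted over the list alone (median 0.81, or 0.79 at the bound). A jasmonate O-methyltransferase (Zm00001eb267640) was at 3.74 ± 1.96 against 0.554 ± 0.234 FPKM and protein TIFY 6a (Zm00001eb179390) at 36.5 ± 12.5 against 15.1 ± 1.95.

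Nitrogen uptake and assimilation genes included 3 that passed adjusted over the list alone. Ammonium transporter 1 member 2 (Zm00001eb247430) had a log2 fold change of 3.54 ± 0.59, a nitrate reductase (Zm00001eb037860) 3.93 ± 0.68 and a probable high-affinity nitrate transporter 2.4 (Zm00001eb162310) 7.62 ± 1.63, from 0.0436 ± 0.0755 to 8.46 ± 5.22 FPKM. The 38 aquaporins, water channels of the membrane, had a median of 1.17, with PIP1-5 (NewGene_12178) at 91.7 ± 27.6 against 16 ± 10.9 FPKM and PIP1-1 (Zm00001eb074210) at 354 ± 63.8 against 122 ± 54.4. The 98 phenylpropanoid genes had a median of 0.94, with probable 4-coumarate--CoA ligase 2 (Zm00001eb187910) at 1.82 ± 0.46 and cinnamoyl-CoA reductase 2 (Zm00001eb316940) at 1.88 ± 0.5. The 81 flavonoid genes had a median of 0.82 (0.76 at the bound), while anthocyanidin 3-O-glucosyltransferase 2 (Zm00001eb322210) was at -4.2 ± 0.82. Adjusted over the list alone, no aquaporin (0) and no phenylpropanoid gene (0) passed, and 1 flavonoid gene was higher and 1 lower.

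As lists, photosynthesis genes were lowest and ribosomal protein genes highest of the 12 libraries in the second library labelled CK resistant. Light harvesting chlorophyll a/b binding protein1 (Zm00001eb357740) was at 1330 ± 749 FPKM under BV-3 against 99.6 ± 104 under CK, with 6.09 in that library. Chlorophyll a-b binding protein 2 (Zm00001eb161410) was at 467 ± 352 against 30.1 ± 38, with 0.635 there. Ribosomal proteins L23 (Zm00001eb194880) and S4 (Zm00001eb082360) were at 13.5 and 13.6 FPKM there, against group means of 6.19 ± 6.3 and 11.3 ± 2.04 under CK. The 20 genes named for the resistant comparison, these included, kept their direction under every alternative, also without that library. The photosynthesis list (median 0.84) had an adjusted p of 2.14e-09, and the ribosomal list (median -0.95) 9.23e-08, against adjusted p = 0.468 and 0.493 with an estimated correlation. No member of either passed adjusted over the list alone (0). Without that library and the 2 whose markers went against their label, the photosynthesis list was no longer called (adjusted p = 0.361) and the ribosomal list was higher rather than lower but not called (adjusted p = 0.175). Without that library alone the ribosomal list had an adjusted p of 0.0629.

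Among resistant libraries edgeR called 0 of 34291 genes, with 3452 at an unadjusted p under 0.05, against 1044 by DESeq2 and 12 by limma. The groups did not overlap in 17.2% of genes, against 10% by chance. Leaving out the 2 libraries whose markers went against their label, or these and the second CK resistant library, gave 0 calls with 3697 and 5272 genes at an unadjusted p under 0.05, and leaving out the third BV-3 susceptible or the second BV-3 resistant library gave 2 and 3. Of the lists 23 were called, 22 higher and 1 lower, with 23 and 13 called in the 2 smaller sets of libraries and 14 without the second CK resistant library alone. None was called by camera with an estimated correlation (adjusted p = 0.223 to 0.493).

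Genes of the LHY and CCA1 class stood higher in the BV-3 than in the CK libraries of both classes. Circadian clock associated2 (Zm00001eb415770) had 120 to 732 FPKM in the 6 BV-3 libraries and 6.31 to 17.5 in the 6 CK libraries, with a log2 fold change of 4.8 ± 0.67 in susceptible (adjusted p = 0.0316) and 5.87 ± 0.7 in resistant libraries (adjusted p = 0.151). An LHY gene (Zm00001eb415760), a morning-phased regulator of the plant clock, had 169 to 1050 FPKM against 11.3 to 34.7, with log2 fold changes of 4.47 ± 0.74 (adjusted p = 0.0378) and 5.05 ± 0.76 (adjusted p = 0.254). Another LHY gene (Zm00001eb172450) had 198 to 1160 against 37.2 to 203, with log2 fold changes of 2.34 ± 0.77 (adjusted p = 0.0843) and 3.49 ± 0.81 (adjusted p = 0.329). Protein REVEILLE 2 (Zm00001eb228670) was at 43.0 ± 11.5 against 8.27 ± 4.31 FPKM among resistant libraries, and had a log2 fold change of 2.46 ± 0.62 there. These 4 were the genes of the clock list higher in resistant libraries when adjusted over the list alone. The list of 52 was not called in either class (adjusted p = 0.888 and 0.512).

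**Figure D3:**
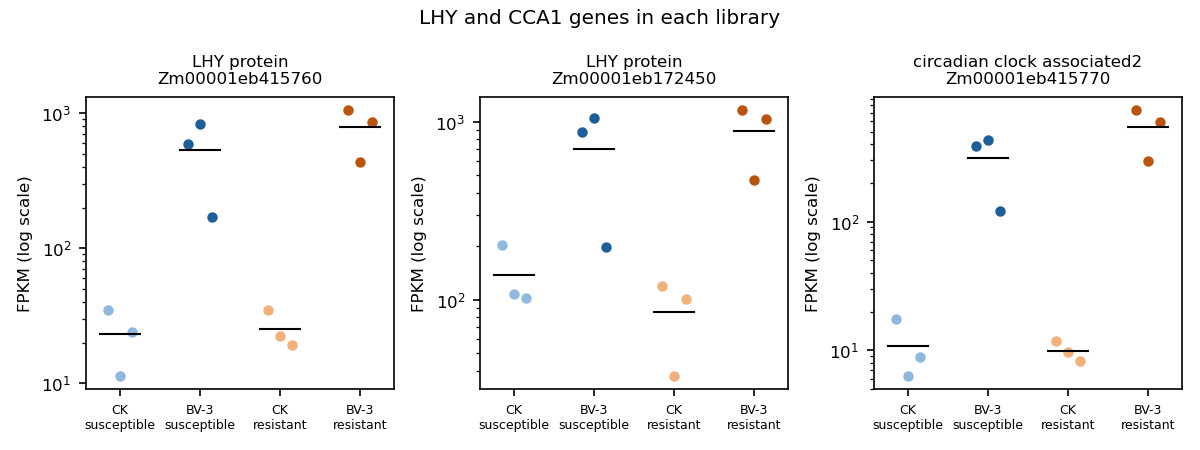
FPKM on a log scale of 3 LHY and CCA1 genes in each of the 12 libraries, with a line at each group mean. For Zm00001eb415770 the BV-3 libraries lie between 120 and 732 and the CK libraries between 6.31 and 17.5.

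Whether BV-3 acted differently on the disease classes was tested as the difference of the BV-3 effects, resistant minus susceptible. Photosynthesis genes had a median difference of 2.25 (88 genes, adjusted p = 9.61e-24, or adjusted p = 0.987 with an estimated correlation). Ribulose bisphosphate carboxylase small subunit 2 (Zm00001eb092540), part of the carbon-fixing enzyme, had 2360 ± 307 FPKM in CK and 452 ± 148 in BV-3 libraries labelled susceptible, and 451 ± 335 and 834 ± 479 in those labelled resistant (difference 3.4 ± 1.12, adjusted p = 0.246). The CK resistant mean includes 78.1 FPKM in the second library, which stood apart. The CK susceptible mean, with its small SD, includes the libraries that carried resistant markers, so the high CK level was not particular to the susceptible line. Aquaporins had a median difference of 0.82 (38 genes), with PIP2-3 (Zm00001eb185300) at 4.71 ± 0.89, the 1 aquaporin that passed adjusted over the list alone. Abscisic acid genes had a median of -0.83, with probable protein phosphatase 2C 9 (Zm00001eb367840), a regulator of abscisic acid signalling, at -2.31 ± 0.6. Jasmonate genes had a median of -0.51, with lipoxygenase9 (Zm00001eb005920) at -1.62 ± 0.52. Ethylene genes had a median of -0.62, with ethylene-responsive factor-like protein 1 (Zm00001eb340140) at -2.37 ± 0.6, and pattern-triggered immunity genes -0.36, with somatic embryogenesis receptor-like kinase 2 (Zm00001eb244860) at -1.52 ± 0.51. No gene of the other 5 lists passed adjusted over the list alone (0).

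For this difference edgeR called 0 genes, with 4688 at an unadjusted p under 0.05, against 1696 by DESeq2 and 0 by limma. These 6 lists were called by camera with the preset correlation, 2 higher and 4 lower, and none with an estimated correlation (adjusted p = 0.987). Without the 2 libraries whose markers went against their label edgeR called 0 genes, with 1510 at an unadjusted p under 0.05, and 0 with 2901 when the second CK resistant library was also left out. Both runs left 1 CK susceptible library, with the spread supplied by the other groups. The photosynthesis (adjusted p = 7.6e-22 and 3.18e-16) and aquaporin lists (3.95e-05 and 4.85e-05) were called there on that 1 library, and the jasmonate (0.662 and 0.458), immunity (0.452 and 0.263) and ethylene lists (0.274 and 0.0552) were not, while the abscisic acid list was called in one of them (0.0839 and 0.0309). Without the first library labelled CK susceptible 2151 genes were called, and without the second 1. The former run kept only CK susceptible libraries that carried resistant markers, so line and BV-3 were mixed in it.

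**Figure D4:**
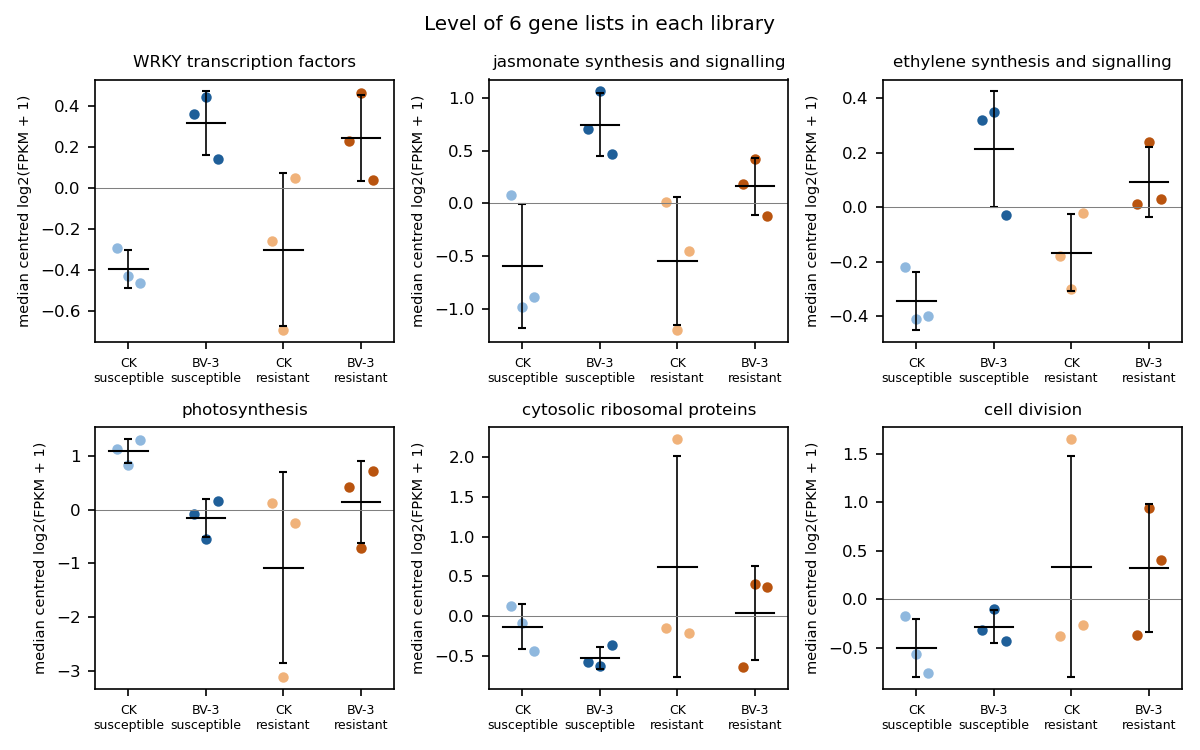
Median over list members of log2(FPKM + 1) centred on each gene's mean over the 12 libraries, for 6 lists, with points for libraries and bars for the mean ± SD of 3. The second library labelled CK resistant stands at -3.13 for photosynthesis and 2.23 for cytosolic ribosomal proteins.

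Libraries labelled resistant and susceptible were compared under CK, where the second and the third library labelled CK susceptible carried resistant markers. Photosynthesis genes were lower in libraries labelled resistant, with a median log2 fold change of -1.97 over 88 genes (adjusted p = 2.28e-34, or adjusted p = 0.601 with an estimated correlation). Photosystem II 5 kDa protein (Zm00001eb245320) had 276 ± 201 FPKM against 1170 ± 112, and ribulose bisphosphate carboxylase small subunit 2 (Zm00001eb092540) 451 ± 335 against 2360 ± 307, with 49.2 and 78.1 in the second library labelled CK resistant. Both genes were high in all libraries labelled CK susceptible, whichever line markers these carried. For these genes the difference thus went with the label rather than with the line markers. Phosphate starvation genes had a median of -0.44, with SPX domain-containing protein 1 (Zm00001eb205600), a phosphate sensor, at 11.7 ± 2.76 against 40.6 ± 13.5 FPKM and GDPD1 (Zm00001eb036910) at 7.83 ± 1.3 against 22.7 ± 7.2, and 1 gene higher and 6 lower adjusted over the list alone. Nitrogen genes had a median of -0.3 and 1 lower gene adjusted over the list alone, with ammonium transporter 1 member 2 (Zm00001eb247430) at 0.231 ± 0.106 against 1.63 ± 0.243. Cytokinin genes had a median of -0.43, with cytokinin oxidase 3 (Zm00001eb363220), which degrades the hormone, at -3.74 ± 0.92. Tyrosine aminotransferase (Zm00001eb201770), caught by the iron list, was at -1.35 ± 0.24. Cell division genes had a median of 1.38 (1.36 at the bound) and ribosomal proteins 0.96, both led by the second library labelled CK resistant, and kinesin-like protein KIN-14F (Zm00001eb396450) was at 9.86 ± 1.29 against 3.83 ± 0.68 FPKM.

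The median over all genes tested was 0.06 with edgeR and 0.28 with limma on log2(FPKM + 1), or 0.36 on TPM. Under CK edgeR called 0 genes, with 5955 at an unadjusted p under 0.05, against 1630 by DESeq2 and 0 by limma. The groups did not overlap in 21.4% of genes, against 10% by chance. Leaving out the 2 libraries whose markers went against their label, which left 1 CK susceptible library assumed to vary like the other groups, gave 1530 calls, and 1874 without the second CK resistant library too. Without the second library labelled CK susceptible alone 2 genes were called. Of 7 lists called by camera with the preset correlation, 2 higher and 5 lower, none was called with an estimated correlation (adjusted p = 0.601 to 0.986). Of the 7 lists only photosynthesis was called in the same direction in both smaller sets of libraries (adjusted p = 1.4e-12 and 1.14e-09). The phosphate (0.476 and 0.539), nitrogen (0.0591 and 0.229), cytokinin (0.0591 and 0.212) and iron lists (0.444 and 0.892) were not called there, and the ribosomal list turned to lower when all 3 were left out (adjusted p = 0.0188) or the second CK resistant library alone (0.0155). The cell division list was lower and not called without that library (0.632), and neither list was called without the third library labelled CK susceptible (0.0541 for both).

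Under BV-3 the line markers of all 6 libraries matched their labels by definition, and the disease classes were compared in the 12-library fit and in a fit of the 6 BV-3 libraries alone. Jasmonate, immunity, ethylene and abscisic acid genes were lower in the resistant libraries as lists with camera's preset correlation (adjusted p = 0.000292 to 0.0204). They were not called with an estimated correlation (adjusted p = 0.875). In the 6-library fit 24 of 75 jasmonate genes were lower and 4 higher, among them a pair of TIFY 10b genes (Zm00001eb168150 and Zm00001eb009620) with 4.01 ± 1.14 against 50.7 ± 14.1 and 1.37 ± 0.674 against 51 ± 13.8 FPKM. Of 106 pattern-triggered immunity genes 25 were lower and 3 higher, with chitin elicitor receptor kinase 1 (Zm00001eb037080), a receptor for fungal chitin, at 17.2 ± 3.11 against 71.4 ± 1.39 FPKM. Of 164 ethylene genes 29 were lower and 5 higher, with ethylene-responsive element binding protein 2 (Zm00001eb193670) at 2.32 ± 0.987 against 42.0 ± 15.6 FPKM. Of 75 abscisic acid genes 19 were lower and 1 higher, with abscisic stress-ripening protein 2 (Zm00001eb131500) at 0.0237 ± 0.041 against 15.5 ± 6.32 FPKM.

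Immune receptors of the NLR class went both ways, with 21 higher and 17 lower of 153 in the 6-library fit. Disease resistance protein RGA5 (Zm00001eb419270) had 0 counts in the BV-3 susceptible libraries and 3.0 ± 0.141 FPKM in the resistant ones, at least 258-fold higher, and putative disease resistance protein RGA4 (Zm00001eb405960) was at 1.64 ± 0.107 against 6.0 ± 0.779. The metal-nicotianamine transporter YSL16 (Zm00001eb287140) was at least 51.2-fold lower in the resistant libraries. The genes with the largest differences had 0 counts in one class, where a lack of expression and a failure to map were not told apart. Higher in the resistant libraries were the RICESLEEPER type gene (NewGene_17548, at least 3460-fold), the NOT complex subunit VIP2 (NewGene_4809, at least 838-fold), GT-3b (NewGene_27524, at least 306-fold), cation/calcium exchanger 4 (Zm00001eb072240, at least 301-fold) and NUP96 (Zm00001eb075600, at least 297-fold). Lower were a beta-tubulin (NewGene_8481, at least 564-fold), a phosphatase 2A subunit (NewGene_16287, at least 563-fold), fiber protein Fb15 (Zm00001eb233510, at least 507-fold), TOM1-like protein 5 (NewGene_23684, at least 477-fold) and UPSTREAM OF FLC (NewGene_5910, at least 303-fold).

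The 12-library fit with edgeR called 0 genes under BV-3, with 7522 at an unadjusted p under 0.05, against 4724 by DESeq2 and 1943 by limma. The 6-library fit called 5349 of 31752 genes, 2179 higher and 3170 lower in the resistant libraries. With all 12 libraries DESeq2 gave 2463 higher and 2261 lower, and limma on log2(FPKM + 1) 885 and 1058, so the balance turned with the method. The 12-library fit called 3981 genes without the 2 libraries whose markers went against their label and 5971 without the second CK resistant library too. It called 4261 without the first library labelled CK susceptible, 270 without the second CK resistant, 4 without the second CK susceptible and 1 without the second BV-3 resistant library. The groups did not overlap in 35.5% of genes, against 10% by chance. In the 12-library fit 7 lists were called, with jasmonate (median -0.88, adjusted p = 0.000292), abscisic acid (-0.59, 0.00901), ethylene (-0.36, 0.0204) and immunity genes (-0.41, 0.0204) lower and ribosomal proteins (0.49, 0.00901), cell division (0.98, 0.00901) and aquaporins (0.62, 0.00901) higher in the resistant libraries. None was called by camera with an estimated correlation (adjusted p = 0.875). All 7 were called in both smaller sets of libraries, which left out no BV-3 library. Of the 7, 4 were called without the third BV-3 resistant library, 5 without the second BV-3 susceptible library, 6 without the first BV-3 susceptible or the second BV-3 resistant library and 5 on log2 CPM. The first BV-3 resistant library was not higher for cell division (-0.37 as median centred log2(FPKM + 1), against -0.43 to -0.1 in the BV-3 susceptible libraries) or ribosomal proteins (-0.64 against -0.63 to -0.37), while the second and the third stood at 0.94 and 0.41, and at 0.4 and 0.37.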

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

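The tests of the second library labelled CK resistant and the runs without doubted libraries were chosen after the result was seen, while the test of the difference was planned. With camera's preset correlation, the BV-3 effect differed between resistant and susceptible libraries in 6 lists. Photosynthesis genes (median difference 2.25, adjusted p = 9.61e-24) and aquaporins (0.82, adjusted p = 0.000183) had a higher effect in the resistant libraries. Abscisic acid (-0.83, adjusted p = 0.00293), jasmonate (-0.51, adjusted p = 0.0359), pattern-triggered immunity (-0.36, adjusted p = 0.0472) and ethylene genes (-0.62, adjusted p = 0.0486) had a lower one. None of the 6 was called with an estimated correlation (adjusted p = 0.987). Without the 2 libraries that went against their label no list was called as lower. The jasmonate list then reversed (adjusted p = 0.662), and the abscisic acid (0.0839), immunity (0.452) and ethylene lists (0.274) were not called. Of the 6 lists 3 were called when the second or the third library labelled CK susceptible, the first or the third CK resistant, the second BV-3 susceptible or the third BV-3 resistant library was left out, and all 6 without the second CK resistant or the third BV-3 susceptible library. Without the first BV-3 susceptible or the second BV-3 resistant library 4 were called, and 5 without the first CK susceptible or the first BV-3 resistant library.

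Chance was not excluded for this difference. Of 100 splits of the libraries 82 gave as many lists as the 6 called, with up to 26 in another split. Splits that exchange BV-3 and CK within a class can carry the BV-3 effect and the line difference, so the shares given here can be too high. At an unadjusted p under 0.05, 16 of 100 splits reached the 4688 genes of the real one. The 0 genes that edgeR called past the threshold (1696 by DESeq2 and 0 by limma) decide nothing, since any split gives as many. Another split called 1844 genes. It exchanged BV-3 and CK in all resistant libraries and in no susceptible one, and so measured the sum of the BV-3 effects in both classes. That sum need not be a shared effect, and it also carries the line difference of the CK susceptible libraries with resistant markers.

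The difference in photosynthesis genes includes the second library labelled CK resistant, without which and the 2 libraries that went against their label the list had an adjusted p of 3.18e-16, a value that rests on 1 CK susceptible library assumed to vary like the other groups. That library had low photosynthesis (-3.13) and high cell division (1.65) and ribosomal protein expression (2.23, all as median centred log2(FPKM + 1)). A wrong line is argued against by the 93.8% of resistant markers present, a shallow library by its total of 30.2 M counts, and a few dominant genes by the 1.67% of counts in its top 10 genes. More dividing tissue in the sample is a candidate explanation, since 97 DNA replication genes outside the cell division list stood at 0.91 against at most 0.49 in the other libraries. Such genes also serve cell division, so their level restates the pattern and is no separate support. The second BV-3 resistant library came nearest, at -0.72 for photosynthesis, 0.94 for cell division, 0.4 for ribosomal protein and 0.49 for DNA replication genes. The labels give no stage or part of the plant for single libraries, so no biological explanation of the design was tested.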

How the results depend on the processing

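The runs without doubted libraries and, for lists, log2 CPM and leaving out 1 library were chosen after the result was seen, while the other settings were planned. Where a result changed the cause was not tested. For BV-3 against CK in susceptible libraries, the 2125 calls became 16813 with limma and array weights, 7010 with DESeq2, 1332 in a fit of the 2 groups alone and 0 at an adjusted p under 0.01. A replicate block left 546, of which 503 were shared, and gave 1 call between the classes under BV-3. Of 18 pairs of libraries with the same replicate number, 3 correlated above 0.1, which gave little ground for such a block. Between CK resistant and BV-3 resistant libraries the correlation was 0.37 for the first, 0.45 for the second and -0.06 for the third. A pairing within the resistant class was thus not excluded. Without the 2 libraries whose line markers went against their label edgeR called 0 genes (2330 at an unadjusted p under 0.05), and 1 without the second library labelled CK resistant too. These runs left 1 CK susceptible library, assumed to vary like the other groups.

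In resistant libraries, where edgeR called 0 genes (3452 at an unadjusted p under 0.05), limma on log2(FPKM + 1) called 12, with pseudocounts of 0.1 and 5 it called 4 and 18, without a filter 15, with a stricter filter 1, with median-of-ratios scaling 2, with quantile normalisation 3, on TPM 9 and with array weights 1429, and DESeq2 called 1044. For the difference of the effects, limma without a filter called 5 genes, with array weights 8760, and DESeq2 1696. Under CK these called 3, 5410 and 1630, and edgeR 1530 and 1874 without the 2 or 3 libraries.

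Between the classes under BV-3, limma called 1943 genes, 2243 and 1597 with pseudocounts of 0.1 and 5, 1941 without a filter, 662 with a stricter one, 2035 with median-of-ratios scaling, 1994 with quantile normalisation, 2039 on TPM and 9612 with array weights. DESeq2 called 4724, the fit of 2 groups 5349, and edgeR 3981 and 5971 without the 2 or 3 libraries.

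Leaving out 1 library gave 0 to 7139 calls in susceptible libraries, 0 to 3 in resistant ones, 0 to 2151 for the difference, 0 to 2 under CK and 0 to 4261 under BV-3. Called lists ranged from 10 to 16, 14 to 25, 3 to 9, 3 to 10 and 4 to 10 in the same order. The highest gene counts for the susceptible libraries, the difference and BV-3 came without the first library labelled CK susceptible (7139, 2151 and 4261). It was the only library of its group whose line markers matched its label, so the counts of 7139 and 2151 mix the line with BV-3.

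With an estimated correlation 0 lists were called in each comparison. On log2 CPM the difference had 3 lists. Without the 3 libraries 13 lists were called in resistant libraries, and under CK 2 without the 2 libraries and 3 without the 3. Of the lists called, 9 of 13 in susceptible libraries, 11 of 23 in resistant ones, 2 of 6 for the difference, 1 of 7 under CK and 3 of 7 under BV-3 were called in all 17 other settings that kept the preset correlation.

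Ribosomal protein S4-3 (Zm00001eb321280) reversed to 0.07 without the 2 and without the 3 libraries. OHP1 (Zm00001eb168820) gave no value there, since all compared libraries were at 0. The ribosomal list reversed in resistant libraries (adjusted p = 0.0629 without the second library labelled CK resistant, 0.175 without the 3, and from 1.56e-15 to 0.0629 over runs without 1 library) and under CK (0.0155 and 0.0188, and from 2.89e-09 to 0.0541 over runs without 1 library). The cell division list reversed under CK (0.632 and 0.141, and from 4.24e-06 to 0.632 over runs without 1 library), and the jasmonate list for the difference without the 2 libraries (0.662). Of 48 genes named for the susceptible libraries, 47 passed, and none but S4-3 reversed where a value could be had. All 47 missed the threshold under at least 1 alternative. That had to be so, since some alternatives called 0 genes, and it tells nothing about single genes.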

Other observations

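The tests of line markers and of clock genes were chosen after the result was seen. KEGG pathways from the table's annotation gave further groups. In susceptible libraries plant-pathogen interaction (739 genes, 45 risen and 13 fallen, median 0.73, adjusted p = 9.68e-05) and alpha-linolenic acid metabolism (93 genes, 10 risen and 2 fallen, median 0.81, adjusted p = 0.000502) were higher under BV-3, and riboflavin metabolism (40 genes, 5 fallen, median -0.56, adjusted p = 9.41e-05) was lower. These had adjusted p = 0.808, 0.854 and 0.808 with an estimated correlation. In resistant libraries photosynthesis antenna proteins (25 genes) had a median of 1.43 (adjusted p = 6.37e-11) and the citrate cycle (105 genes) -0.48 (adjusted p = 0.000158), both at adjusted p = 0.655 with an estimated correlation. No KEGG pathway was tested without the second library labelled CK resistant. Nor was any tested without the 2 CK susceptible libraries whose line markers went against their label. Line and BV-3 were therefore not separated in the pathways of the susceptible libraries. Under BV-3 DNA replication genes (115) had a median of 0.77 in resistant against susceptible libraries (adjusted p = 0.0183, or adjusted p = 0.987 with an estimated correlation).

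The second and the third library labelled CK susceptible carried at least 94.4% of the resistant line markers, which a wrong line in these libraries predicts and which is a candidate explanation. An exchange with libraries labelled CK resistant is argued against, since each of those carried at least 93.8% of the resistant markers. A mixture of both lines is argued against by the at most 1.6% of susceptible markers present, and a response of susceptible plants to BV-3 by the 98% present in the first library labelled CK susceptible. Where the wrong plants or RNA came in was not tested.

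The 3 LHY and CCA1 genes with a mean of at least 1 FPKM had a mean log2(FPKM + 1) of 9.03 ± 0.95 in 6 BV-3 and 4.89 ± 0.5 in 6 CK libraries (2-sided exact permutation p = 0.00216, the smallest that 924 splits can give). The class was singled out because of these values, so this p restates the pattern and is no further evidence for it, and the clock list of 52 genes was not called (adjusted p = 0.888 in susceptible and 0.512 in resistant libraries). Library depth (ratio 1.15, BV-3 over CK) and a wrong line (fold changes of at least 3.49 on the log2 scale in the resistant libraries) are argued against. Harvest at another time of day and a change of the clock by BV-3 cannot be told apart, since both predict the lower TOC1 class (-0.8, exact p = 0.0368) and the labels give no times. A different time of harvest would enter every gene and list of the BV-3 against CK comparisons. The third BV-3 susceptible library had 229 FPKM of gigantea1 against at most 11.1 in the other BV-3 libraries, and may have been harvested later, which stays open for 1 library.

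For the comparisons of 3 against 3 libraries, 10 splits cannot give a share under 0.05 (the smallest is 0.1). Among genes the real split and the highest other called 2125 and 0 in susceptible libraries, 0 and 0 in resistant ones, 0 and 1 under CK and 0 and 0 under BV-3 with edgeR, with 9154 and 5303, 3452 and 5160, 5955 and 5062, and 7522 and 1125 at an unadjusted p under 0.05. Among lists they called 13 and 17, 23 and 24, 7 and 17, and 7 and 16. DESeq2 called 1044, 1630 and 4724 genes in the last 3 comparisons for the real split, and limma 12, 0 and 1943.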
